A study of Homo sapiens with 4 samples.

How the data were processed

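γH2AX ChIP-seq peak lists of 4 SK-UT-1 libraries were analysed, 1 each for DMSO, OTS186935, doxorubicin and the combination. Per the labels' protocols, cross-linked chromatin was sheared by sonication, precipitated with an antibody against phosphorylated H2A.X, and made into libraries with a ThruPLEX DNA-Seq kit. The submitters' processing notes name Bowtie2 2.4.2, Picard 2.25.3, bedtools 2.30.0, MACS2 2.2.7.1 and the genome build hg38, without saying what each did; filters, peak calling options and any input control are not given in the sources used here. Each deposited list held 1 row per summit with positions, a fold enrichment over local background, the −log10 p and −log10 q, and a score. The fold, a ratio, the −log10 values and the score are the authors' deposited values, as the columns of this peak format define them. In the deposited lists the score equalled the whole part of 10 times the −log10 q in nearly all rows. The number of rows was 76870 with DMSO, 62008 with OTS186935, 48594 with doxorubicin and 29619 with the combination, with a lowest −log10 q of 1.0 in each and lowest −log10 p values of 2.74, 2.81, 2.92 and 3.08. There was 1 list per library.

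Rows that overlapped or touched within a list were merged, keeping the highest values, and chromosomes 1 to 22 and X were analysed. The depth is not stated, so the fragment pileup at each summit and the local background were solved from the deposited fold and −log10 p as MACS2 defines them (fold as pileup + 1 over background + 1, and a Poisson p). The pileup came out whole, within 0.05 fragments, for 100% of rows. Rows in which a second whole pileup matched the −log10 p within 0.002 numbered 576 with DMSO, 2109 with OTS186935, 423 with doxorubicin and 1402 with the combination. The commonest background, its floor, was taken as a measure of relative depth. Above the floor, background values were spaced by the length of the shortest listed peak divided by 10 kb, the step expected of a background drawn from the library's own surroundings, and no scaled input was visible in the values. Estimated fragments assume a genome size of 2.7 Gb, the MACS2 preset.

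Peaks of 2 lists were called shared when they overlapped by at least 1 bp. Each list was placed at random 100 times on the same chromosomes with bedtools 2.31.1, without leaving out assembly gaps. Gene positions came from an NCBI RefSeq table of the same genome assembly, which gives extents without strand, exons or transcripts, and no genome sequence was used. The promoter planned before the data were examined, 1 kb around the 5′ end, was therefore replaced by windows of 1 kb either side of both ends of each of 19970 protein-coding genes, called gene ends here, so a gene-end peak can lie at the 5′ or the 3′ end. Exons and introns were not told apart, random lists were not matched on GC content, and chromosome lengths are the highest coordinates in the gene table or the lists. Shares carry exact Clopper-Pearson 95% intervals.

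The 5 comparisons, 18 gene lists and the rule for named genes were fixed before the data were examined. That rule took, per comparison and direction, the 8 genes of highest fold whose gene-end peak had −log10 q of 5 or more and no peak of the other library in the window, the 5 genes of highest fold per library, and up to 4 members per list by fold in DMSO. Other list members named beside them were picked after their values were seen, to show which members had a peak. Not every gene the rule took is named. Genes sharing a window were named together, and genes of near-identical families as uncertain. For 17 lists, the share of genes with a DMSO gene-end peak that also had 1 in a treated library, whether or not the peaks overlapped, was placed among 10000 random lists matched on the decile of the DMSO −log10 q; percentiles describe these libraries and are not tests of the conditions. The percentiles are mid-ranks, in which random lists tied with the list count in part. Outside the central 95% means here a percentile below 2.5 or above 97.5. Fragile site genes were compared by peaks per Mb of gene body with random lists matched on the decile of gene length. Alternatives were −log10 q limits of 5 and 10, a reciprocal overlap of 50%, joining peaks within 1 kb, all contigs, windows of 2.5 kb, lists of equal length by −log10 p, and binomial thinning of the solved pileups to the lowest floor with the strictest −log10 p limit of the lists; 6 more were added later and are named as such in the closing section. On simulated data, 100% of 4000 whole pileups were recovered, 18.9% of fractional pileups came out within 0.05 of a whole number, overlaps matched bedtools with a difference of 0, 4% of random lists of 20 genes without planted loss lay outside the central 95%, and 94.5% of lists with 70% of kept genes dropped lay below percentile 2.5. Most lists here had fewer than 20 genes with a DMSO peak, down to 5, and the sensitivity at those sizes was not simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.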

Results

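The phosphorylated histone H2A.X (γH2AX), a chromatin mark laid down around DNA double-strand breaks, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in SK-UT-1, a cell line derived from a uterine leiomyosarcoma, a malignant tumour of smooth muscle. Cells received 0.1% DMSO as the vehicle, 1 µM OTS186935, an inhibitor of the histone H3 lysine 9 (H3K9) methyltransferase SUV39H2, 0.5 µM doxorubicin, a topoisomerase II poison, or OTS186935 and doxorubicin together at those doses (the combination). The series title speaks of a PARP inhibitor, while the drug paired with OTS186935 in these libraries was doxorubicin. Each condition had 1 library, so there were no replicates, no difference between conditions was tested, and values are compared side by side. Intervals beside shares are exact 95% binomial intervals and cover counting error only.

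Peaks were fewest with both drugs together. After intervals that overlapped or touched were merged, chromosomes 1 to 22 and X held, in peaks, 72858 with DMSO, 59710 with OTS186935, 47495 with doxorubicin and 29213 with the combination. The treated libraries thus had 18%, 34.8% and 59.9% fewer peaks than DMSO in that order. Each peak is an enrichment over local background, so the number of peaks does not measure the total amount of γH2AX. Covered length was 39.5, 31.1, 22.2 and 13.2 Mb, and median peak width was 465, 448, 405 and 397 bp. The shortest listed peak also differed, at 331, 323, 295 and 296 bp, and neither width nor covered length was corrected for this. Peaks with a −log10 q of 5 or more numbered 18655 with DMSO, 10592 with OTS186935, 4762 with doxorubicin and 2475 with the combination. The genome-wide background solved from the peak values was 0.454, 0.397, 0.389 and 0.428 fragments per position, so the library with the fewest peaks did not have the lowest background. All libraries were shallow: if the peak caller's preset human genome size was used, these backgrounds correspond to 3.7, 3.31, 3.55 and 3.9 M fragments, and 99% of peaks had a summit of 28, 27, 21 and 16 fragments or fewer.

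**Figure D1:**
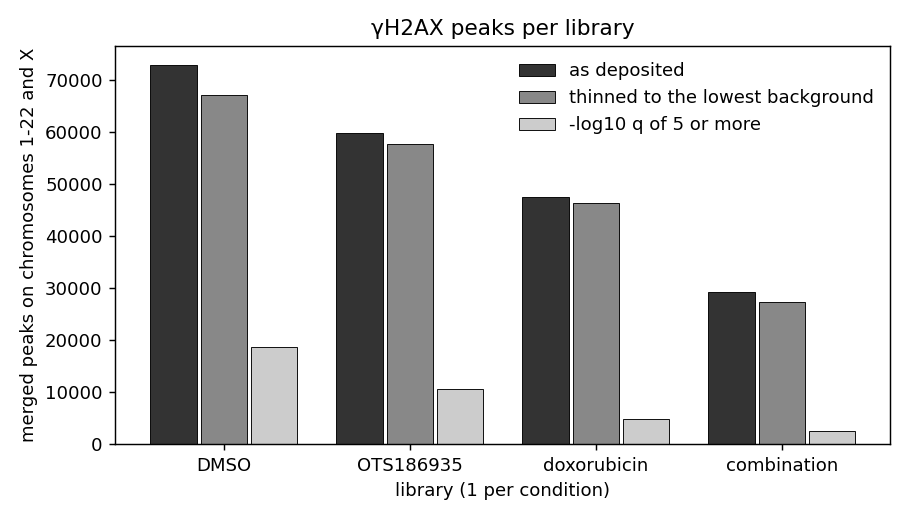
Merged peaks per library on chromosomes 1 to 22 and X (vertical axis, number of peaks) for the 4 libraries (horizontal axis), with bars for the lists as deposited, after thinning to the lowest background, and for peaks with −log10 q of 5 or more. The bars as deposited descend from 72858 with DMSO to 29213 with the combination, and the other bars keep that order.

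In every library, peaks lay near the ends of protein-coding genes and of chromosomes more often than randomly placed intervals did. No input library was among the lists, and assembly gaps were not left out of the random placements. How much of this enrichment belongs to γH2AX itself was therefore not tested. Windows of 1 kb either side of either annotated end of a gene held 9.23% of peaks with DMSO, 8.17% with OTS186935, 7.9% with doxorubicin and 8.63% with the combination, 3.36, 2.98, 2.95 and 3.24 times the mean of 100 random placements. The terminal 5 Mb of chromosomes held 17%, 17.4%, 16.8% and 16.2% of peaks, against 8.28% of placements of the DMSO peaks. Density in DMSO was 82.6 peaks per Mb in the outermost 0.5 Mb and 28.4 per Mb at 10 to 20 Mb from the end. Gene-dense chromosome 19 had the highest density in each library, in peaks per Mb 60.2 with DMSO, 49.5 with OTS186935, 34.8 with doxorubicin and 20.1 with the combination, and chromosome 13 the lowest, with 7.41, 5.77, 4.74 and 2.03. Of 19970 protein-coding genes, 7737 with DMSO, 5737 with OTS186935, 4367 with doxorubicin and 2946 with the combination had a gene-end peak. The strongest were at PLAAT5 (11.9-fold), VAMP7 of the pseudoautosomal region (11.4-fold), PF4, STK31 and ZSCAN12 in DMSO, at PCMTD2 (11.7-fold), LOC124902393, ZSCAN12, ADNP2 and ZNF311 with OTS186935, at OR2T10 (11.5-fold), GIMAP7, TKTL2, INSL6 and ZNF534 with doxorubicin, and at SCAF4 (11-fold), MEI4, LONRF1, ZNF772 and CASR with the combination. Fold enrichment over local background is the authors' value for each peak and only ranks peaks within a list.

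Joined over the libraries, the peaks formed 123975 regions, of which 9128 (7.36%) were called in all 4. Genes with a gene-end peak in every library, not always at the same site or the same end, included DES, which encodes the muscle filament protein desmin, the recombination gene RAD54L, the H3K9 methyltransferase gene EHMT2, and the neuronal genes SYT1, NEFL and ELAVL4.

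The comparison of OTS186935 with DMSO asked where γH2AX peaks lay with the SUV39H2 inhibitor. Smooth muscle genes had gene-end peaks at 11 of 20 with DMSO and 11 of 20 with OTS186935, percentiles 92.8 and 99.2 of random lists of all genes, of which 38.7% and 28.7% had 1. In all, 8 of 11 of those with a DMSO peak had 1 with OTS186935 as well, among them DES (7.15-fold and 5.8-fold) and ACTA2, the smooth muscle actin gene (7.22-fold and 4.3-fold). The contractile gene CNN1 (5.2-fold) had its peak in DMSO alone of these libraries. Genes of H3K9 methylation and heterochromatin had gene-end peaks at 11 of 26 with DMSO and 2 of 26 with OTS186935. MORC2 (5.52-fold in DMSO), CBX3, HDAC2 and KDM4C had none in any treated library, and ATRX and EHMT2 had 1 with the inhibitor. The list had 3 of 26 with doxorubicin and 1 of 26 with the combination. Among random lists of all genes these lay at percentile 64.3 in DMSO, 0.54 with OTS186935, 10 with doxorubicin and 5.04 with the combination. Immediate early genes are induced within minutes of a stimulus, and their list here also holds other stress genes. Of these immediate early and stress genes, 20 of 28 had a gene-end peak with DMSO and 8 of 28 with OTS186935. FOS (5.46-fold in DMSO), EGR1 and IER2 had none with the inhibitor, and JUN, HSPH1 and CCN2 had 1 in both. Against random lists of all genes that list lay at percentile 99.97 in DMSO and at 51.3, 7.21 and 28.9 with OTS186935, doxorubicin and the combination, so DMSO was the library that stood apart. Replication-dependent histone genes, whose likeness to each other makes the placing of reads uncertain, had gene-end peaks at 33 and 17 of 69, percentiles 93.8 and 22.6 of random lists of all genes.

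Set against random lists of genes with DMSO peaks of like −log10 q, the share of genes that had a gene-end peak in both libraries (the share kept, whether or not the peaks overlapped) lay with OTS186935 at percentile 2.85 for the H3K9 list (2 of 11), 3.77 for immediate early genes (8 of 20), 1.82 for histones (13 of 33), 3.45 for ribosomal protein genes (13 of 32) and 85 for smooth muscle genes. Of the 17 lists, only the histones lay outside the central 95% of random lists by percentile. Their share, 39.4%, equalled the lower edge of that range. Neighbouring histone genes share peaks, and with list genes that share a peak counted once, a choice made after the data had been seen, the histones lay at percentile 10.5 (11 of 25), inside that range, and the H3K9 list, which shares none, at 2.48, just outside it. The H3K9 list lay inside at 10.9 (6 of 14) with windows of 2.5 kb and 5.08 after thinning. It also lay inside at 4.9 with matching on local background and 4.045 with a common p limit. Ribosomal protein genes lay at 1.97 (24 of 48) with windows of 2.5 kb, and immediate early genes at 2.02 with matching on local background. Other settings moved these lists further inside the range: immediate early genes lay at 40.5 (15 of 24) with windows of 2.5 kb, and ribosomal protein genes at 6.235 (13 of 31) after thinning. Over all peaks, 32383 of 72858, or 44.4% (95% interval 44.1 to 44.8), of DMSO peaks overlapped an OTS186935 peak, against 2.34% of random placements and 3.96% after shifts of 50 to 500 kb (local shifts, added after the data had been seen). In turn, 54.3% of OTS186935 peaks overlapped a DMSO peak. Gene-end peaks were present in both libraries at 4368 genes, in OTS186935 only at 1369 and in DMSO only at 3369, where independent sets would share 2223. With lists of equal length, the percent of DMSO peaks found in OTS186935 was 42.9, genes with a gene-end peak in OTS186935 and not in DMSO numbered 1349 and genes with a gene-end peak in DMSO and not in OTS186935 numbered 1647. Among the strongest found with OTS186935 only were those at CRADD (chromosome 12, 93894514 to 93894916; fold enrichment 9.03, −log10 q 10.4), ALMS1, IFI27L2, GTF2A1L, ERICH3, SLC25A51 and TDRD15. Those found with DMSO only were at PF4 (chromosome 4, 73981715 to 73982162; fold enrichment 11, −log10 q 14.9), KCNJ18, GLRX2, ZNF26, TNFRSF10D, SCNN1G, WWOX and SMIM28. These peaks rested on summits of 11 to 15 and 13 to 23 fragments. KCNJ18 belongs to a group of near-identical channel genes and its position is uncertain.

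Doxorubicin was compared with DMSO to show where γH2AX peaks lay under a known DNA-damaging drug. Immediate early and stress genes had gene-end peaks at 20 of 28 with DMSO and 3 of 28 with doxorubicin: FOS, EGR1, CCN1, KLF6, JUN and HSPH1 (6.4-fold in DMSO) had none with the drug, and JUNB, DUSP1 and ZFP36 did. Interferon response genes had gene-end peaks at 7 of 25 with DMSO and 1 of 25 with doxorubicin, MX1 (7.19-fold in DMSO) and IFI27 (6.87-fold) having none with doxorubicin and BST2 (4.4-fold) having 1. Among random lists of all genes the interferon list lay at percentile 14 with DMSO and 0.925 with doxorubicin, and zinc finger genes of chromosome 19 at 11.5 and 0.86. Neuronal genes, which serve here as a comparison list, had 7 of 12 in both libraries.

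The share kept lay at percentile 0.10 of matched random lists for immediate early genes (3 of 20), 0.985 for zinc finger genes of chromosome 19 (29 of 84), 1.58 for ribosomal protein genes (8 of 32), 3.38 for interferon response genes (1 of 7) and 96.7 for neuronal genes (6 of 7). Matched on local background as well, a choice made after the data had been seen, the zinc finger genes lay at percentile 4 and the ribosomal protein genes at 2.79, both inside the central 95% of random lists, and the immediate early genes at 0.015. With windows of 2.5 kb the immediate early list lay at percentile 17.4 (10 of 24 kept), inside the range of random lists. Of DMSO peaks, 25561 of 72858, or 35.1% (95% interval 34.7 to 35.4), overlapped a doxorubicin peak, against 1.74% at random and 2.87% after local shifts, and 54.1% of doxorubicin peaks overlapped a DMSO peak. Genes with a gene-end peak in both libraries numbered 3426, against 1692 for independent sets, with 941 in doxorubicin only and 4311 in DMSO only. For lists of equal length, the percent of DMSO peaks found in doxorubicin was 40.3, genes with a gene-end peak in doxorubicin and not in DMSO numbered 1363 and genes with a gene-end peak in DMSO and not in doxorubicin numbered 1742. With doxorubicin only, the strongest were at EXOC1L (chromosome 4, 55819558 to 55819931; fold enrichment 8.23, −log10 q 8.34), FAM13C, RPS23, a ribosomal protein gene, ZNF19, ZSWIM2, SERPINB5, KRTAP12-3 and EPB42, with summits of 9 to 15 fragments. With DMSO only they were at STK31 (chromosome 7, 23709933 to 23710560; fold enrichment 10.6, −log10 q 14.3), the iron transporter gene SLC11A2, KCNJ18, GALK2, GLRX2, SCNN1G, WWOX and the tumour suppressor gene TSC1 (9.08-fold), with summits of 13 to 19 fragments.

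The combination was compared with DMSO for the joint exposure. Of genes altered in leiomyosarcoma, 5 of 17 had a gene-end peak with DMSO, among them ATRX and CCNE1 (5.47-fold), and 0 of 17 with the combination, where of all genes 38.7% and 14.8% had 1. Homologous recombination and damage signalling genes had 7 of 32 and 2 of 32: RAD54L had 1 in both (6.14-fold and 4.94-fold), RPA1, PALB2, RAD51C and H2AX had 1 with DMSO and not with the combination, and RNF8 had 1 with the combination and not with DMSO. That list lay at percentile 2.23 of random lists of all genes in DMSO and at 8.45 in the combination. PARP and end joining genes had 5 of 22 and 2 of 22, APTX having 1 in both and NHEJ1 with the combination and not with DMSO. Histone genes had 33 of 69 with DMSO and 17 of 69 with the combination, and 14 of 33 of those with a DMSO peak had 1 in both, including H4C9 and H1-3. With the combination they lay at percentile 98.4 of random lists of all genes, and ribosomal protein genes, with 6 of 85, at 1.6. Of neuronal genes with a DMSO peak, 5 of 7 had 1 in both: SYT1 (6.55-fold and 6.11-fold), NEFL, NEFM, ELAVL4 and SYN1.

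Against matched random lists, the share kept in the combination lay at percentile 1.91 for interferon response genes (0 of 7), 3.27 for immediate early genes (3 of 20), 3.0 for ribosomal protein genes (5 of 32), 7.81 for genes altered in leiomyosarcoma (0 of 5, the lowest value so short a list can take), 22 for homologous recombination and damage signalling (1 of 7), 39.4 for PARP and end joining (1 of 5), 92.5 for histones and 96.1 for neuronal genes. Windows of 2.5 kb put the leiomyosarcoma list at 2.08 (0 of 6) and histones at 98.4 (22 of 43), thinning put immediate early genes at 1.36 (2 of 20), and counting genes that share a peak once in the random lists put ribosomal protein genes, which share none, at 2.3 (5 of 32), all outside the central 95%. The same wide windows put immediate early genes at 41.2 (8 of 24) and ribosomal protein genes at 30.8 (15 of 48), well inside. The interferon list and, with wide windows, the leiomyosarcoma list kept no gene, the lowest value each could take. With 0 of 7, the interferon share equalled the lower edge of the central 95%. Histone genes share peaks, which were not counted once at 2.5 kb, so 98.4 may overstate how far they stood apart. Of DMSO peaks, 17220 of 72858, or 23.6% (95% interval 23.3 to 23.9), overlapped a combination peak, against 1.05% at random and 1.75% after local shifts. The reverse share, of combination peaks that overlapped a DMSO peak, was 59.3%. Gene-end peaks were found in both at 2433 genes, against 1141 for independent sets, in the combination only at 513 and in DMSO only at 5304. These values depend on the shorter list of the combination. Cut to equal length, the lists gave nearer values: the percent of DMSO peaks found in combination was 35.8, genes with a gene-end peak in combination and not in DMSO numbered 1433 and genes with a gene-end peak in DMSO and not in combination numbered 1828. The strongest with the combination only were at GLRA3 (chromosome 4, 174829071 to 174829447; fold enrichment 8.41, −log10 q 8.12), CTAGE1, TDRD15, KIF4B, BCAS1, BATF3, SLC25A51 and AKAP6, with summits of 9 to 15 fragments. With DMSO only they were at ZNF597 (chromosome 16, 3431771 to 3432140; fold enrichment 10.5, −log10 q 13.4), KCNJ18, TMLHE with its neighbour SPRY3, PRKCE, IQCF6, TOPAZ1 and ZNF180, with summits of 13 to 23 fragments. CTAGE1 and KIF4B resemble other genes closely, so their peaks are uncertain.

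**Figure D2:**
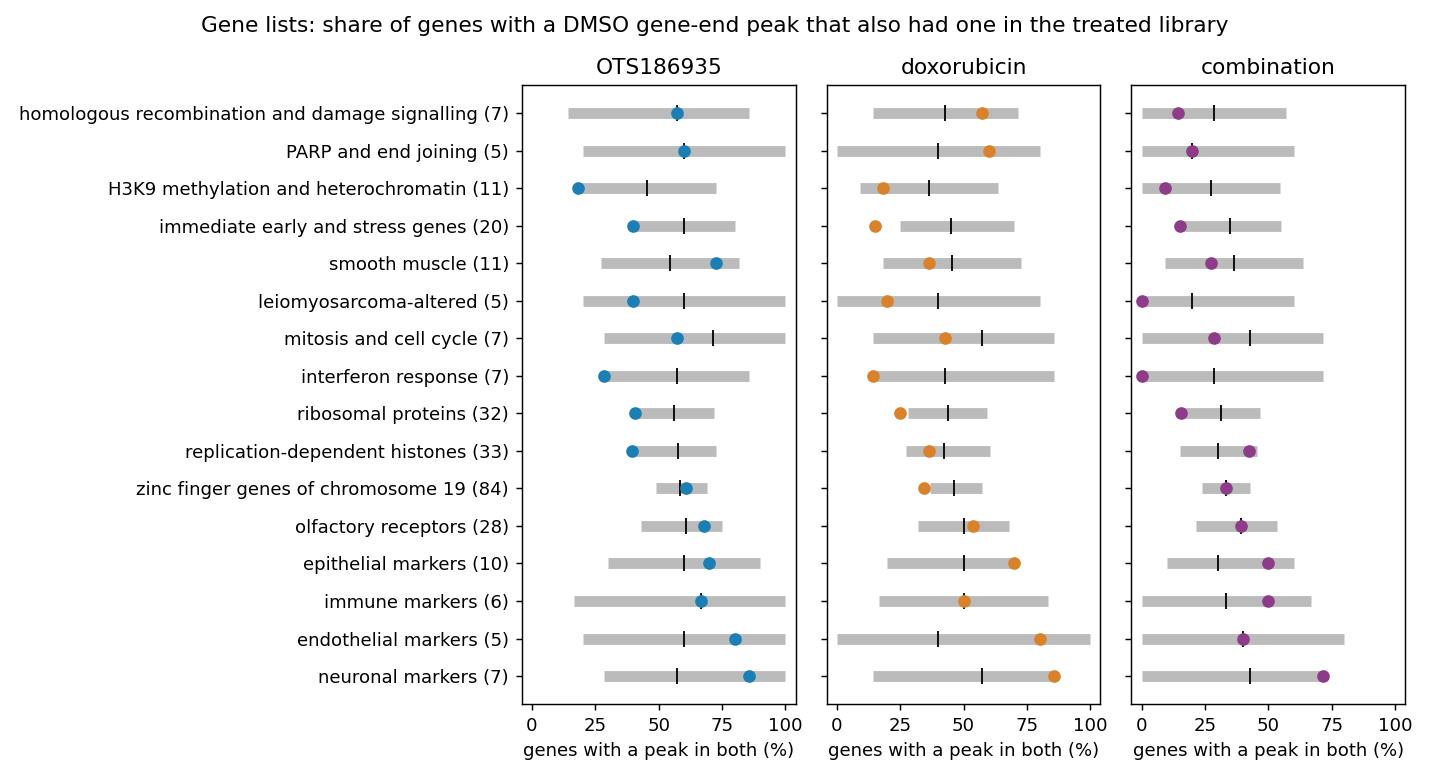
Share of genes with a DMSO gene-end peak that also had 1 in each treated library (horizontal axis, percent) for 16 of the 17 gene lists (vertical axis, number of genes with a DMSO peak in parentheses). Points are the lists, ticks the median and grey bars the central 95% of 10000 matched random lists. A point on the lower edge of its bar can have a percentile below 2.5, since percentiles are mid-ranks. The immediate early genes sit at 15% with doxorubicin, where random lists had a median of 45%.

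Setting the combination against doxorubicin alone shows the libraries with and without OTS186935 under the same dose of doxorubicin. Histone genes had gene-end peaks at 14 of 69 with doxorubicin and 17 of 69 with the combination, H2BC13, H2AC13 and H2BC14 having 1 with the combination and DMSO but not with doxorubicin. Of all genes, 21.9% and 14.8% had a gene-end peak. Mitosis and cell cycle genes had 6 of 26 and 2 of 26, percentiles 57.6 and 16.1 of random lists of all genes. CDC20, CDC6, AURKB and WEE1 had 1 with doxorubicin and not with the combination, and MKI67 the reverse. AURKB (5.05-fold) and MKI67 (5.28-fold) had 1 with DMSO as well. Epithelial genes had 8 of 15 and 5 of 15, with CLDN3, CLDN7, GRHL2 and KRT5 in both. Of doxorubicin peaks, 12987 of 47495, or 27.3% (95% interval 26.9 to 27.7), overlapped a combination peak, against 0.956% at random and 1.58% after local shifts. A gene-end peak was present at 1858 genes in both libraries, 1088 in the combination only and 2509 in doxorubicin only. At equal length, the percent of doxorubicin peaks found in combination was 34.6, genes with a gene-end peak in combination and not in doxorubicin numbered 1477 and genes with a gene-end peak in doxorubicin and not in combination numbered 1493. The strongest with the combination only were at ZNF772 (chromosome 19, 57477122 to 57477541; fold enrichment 8.64, −log10 q 8.59), GLRA3, CTAGE1, BCAS1, RITA1, LCE4A, C4orf36 and SLC25A51. With doxorubicin only they were at OR2T10 (chromosome 1, 248590073 to 248590394; fold enrichment 11.5, −log10 q 15), the immune GTPase gene GIMAP7, ZNF534, ZNF180, SH3YL1 with its neighbour ACP1, and TMLHE with SPRY3. OR2T10, LCE4A and the zinc finger genes belong to families of similar sequence, so the placing of their reads is uncertain.

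The combination was also set against OTS186935 alone, the libraries with and without doxorubicin at the same dose of inhibitor. Smooth muscle genes had gene-end peaks at 11 of 20 with OTS186935 and 4 of 20 with the combination (percentiles 99.2 and 75 of random lists of all genes). DES, CALD1 and PDLIM3 had 1 in both. ACTA2, ACTG2, MYOCD, the gene of a smooth muscle transcription factor, and SMTN had 1 with OTS186935 and not with the combination. ACTA2 and SMTN had 1 with DMSO as well. Ribosomal protein genes had 21 of 85 and 6 of 85, and zinc finger genes of chromosome 19 62 of 240 and 33 of 240. Of all genes, 28.7% and 14.8% had a gene-end peak. Against random lists of all genes the ribosomal list lay at percentiles 20.65 and 1.6, and the zinc finger list at 15.7 and 33.7. Histone genes had the same number in each library, 17. Of OTS186935 peaks, 15335 of 59710, or 25.7% (95% interval 25.3 to 26), overlapped a combination peak, against 1.04% at random and 1.73% after local shifts. Of genes, 2162 had a gene-end peak in both, 784 in the combination only and 3575 in OTS186935 only. With lists of equal length the counts were close: the percent of OTS186935 peaks found in combination was 35.8, genes with a gene-end peak in combination and not in OTS186935 numbered 1452 and genes with a gene-end peak in OTS186935 and not in combination numbered 1549. With the combination only, the strongest were at CTAGE1, NLRP1 (chromosome 17, 5583471 to 5583832; fold enrichment 7.6, −log10 q 7.14), LCE4A, C4orf36, ACOX2, PF4, SERPING1 and ATP6V0A4 with its neighbour TMEM213. With OTS186935 only they were at PCMTD2 (chromosome 20, 64254443 to 64255416; fold enrichment 11.7, −log10 q 30.9), ZNF311, PARP15, SCAND3, COX8C, OR2T10, ZNF799 and TEX12.

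Long genes at common fragile sites, regions prone to breakage under replication stress and among them FHIT, WWOX and MACROD2, held, in peaks per Mb of gene body, 11.2 with DMSO, 8.43 with OTS186935, 7.16 with doxorubicin and 3.85 with the combination. The 24 genes of this list lay at percentile 0.090 in DMSO among random lists matched on length decile, whose median was 21.9 peaks per Mb. Those random genes were much shorter, with a median length of 249 kb against 1470 kb. Among the genes nearest in length the list lay at percentile 49.2 with DMSO, 38.6 with OTS186935, 38.5 with doxorubicin and 13.7 with the combination, so no difference beyond gene length was found.

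**Figure D3:**
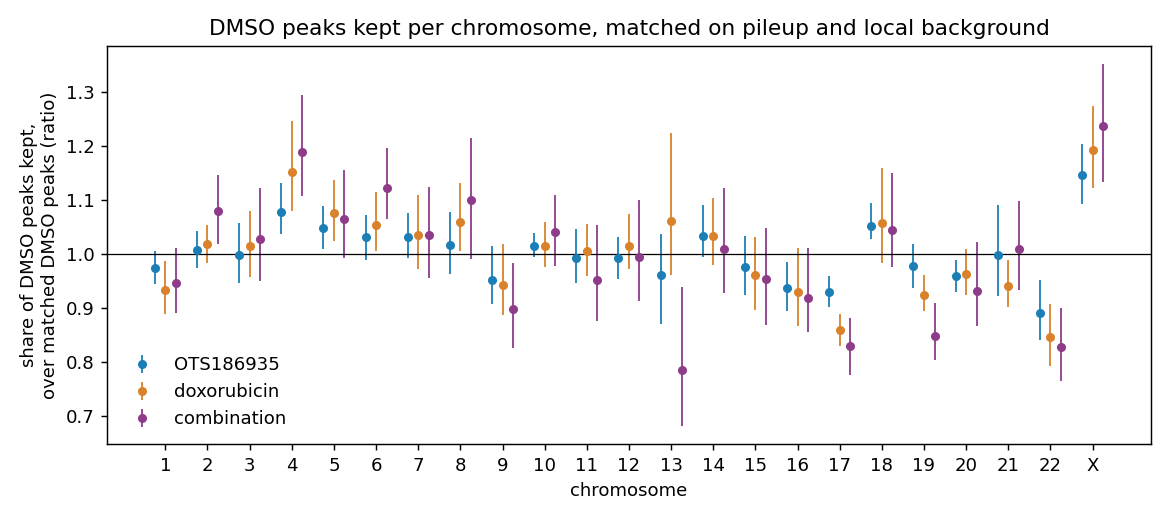
Share of DMSO peaks kept in each treated library relative to DMSO peaks of equal pileup and local background (vertical axis, ratio) for chromosomes 1 to 22 and X (horizontal axis), with intervals from 5 Mb blocks and 1 marker per treated library. In the combination the ratio was lowest for chromosome 13, at 0.785, and highest for X, at 1.24, with 0.83 for chromosome 17.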

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

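The tests on depth and on spread were set before their results were seen; those on chromosomes and on immediate early genes were chosen only after results had been seen. An earlier version of the pattern of immediate early genes had included the H3K9 genes, which in the planned setting lay inside the range of random lists in every treated library. The prediction first written for equal weakening used gene lists: 5 of 51 shares kept (9.8%) lay outside the central 95% of random lists, which met its limit of 15%, and 4.92% of simulated sets of random lists had as many. The test by chromosome was added after the shares by chromosome had been seen, so neither decides alone.

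The fewer peaks of the treated libraries were weighed against technical explanations. DMSO thinned to the background of the combination kept 2.26 times the combination's number of peaks (mean of 20 draws, 65888 peaks). Thinned further, to the lowest background, it kept more, 67061, so counts after thinning do not follow depth alone and the factor is rough. Both counts stood far above the 29213 of the combination, which argues against depth as the sole cause there. This test was not run for the single drugs, whose backgrounds were lower than that of the combination. With every library thinned to the lowest background, peaks numbered 67061 with DMSO, 57687 with OTS186935 and 46238 with doxorubicin. How much of those smaller differences depth explains was not decided. Weaker enrichment of all sites alike stays open: the gene lists met its limit, while 39.1% of chromosomes (9 of 23) had a share kept in the combination that differed from DMSO peaks of equal pileup and local background, with ratios of 0.83 (0.777 to 0.883) for chromosome 17 and 1.24 (1.13 to 1.35) for X. Of the 9 chromosomes, 5 were lower and 4 higher, and the lowest ratio was 0.785 (0.682 to 0.939), for chromosome 13. At the regions called in all 4 libraries, median fold was 5.47 with DMSO, 5.08 with OTS186935, 4.76 with doxorubicin and 4.52 with the combination. Those regions are selected for being called, and fold only ranks peaks within a list, so these values do not decide. Signal spread over the surrounding 10 kb also stays open: at the 9128 regions called in all 4 libraries, local background over floor in the combination was 0.876 times that in DMSO (median, interval 0.868 to 0.885), but sites still called there are selected for a low background. Over all peaks of each library, its median was 1.57 in DMSO and 1.73 in the combination, while its 75th percentile was 3.61 and 3.05. A library-specific bias by GC content, a poorer precipitation and an effect of the drugs stay open, since each condition had 1 library and no genome sequence was used. Peaks over local background cannot show a change of the mark over wider stretches or the whole genome, which was not tested.

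Immediate early genes with a DMSO gene-end peak had 1 in doxorubicin less often than matched genes, at percentile 0.10, the lowest of 51 such values. Matching also on local background left them at percentile 0.015, which argues against a dense background, and 1.93% of simulated sets had a lowest value as low, which argues against a pick among many lists. With windows of 2.5 kb they lay at percentile 17.4, so the narrow window may account for the pattern. An unusually high number of peaks at these genes in the DMSO library itself (percentile 99.97 of random lists of all genes) and an effect of doxorubicin stay open and untested.

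The number of histone genes with a gene-end peak differed by -16 between OTS186935 and DMSO and by 3 between the combination and doxorubicin, so the direction was opposite with and without doxorubicin, a gap of 19 genes that was not tested. Histone genes share peaks, and their distinct peaks numbered 25 with DMSO, 14 with OTS186935, 11 with doxorubicin and 13 with the combination, a smaller gap in the same directions. The endothelial list differed by 1 and by -1 gene, a gap of -2, also not tested. Outside chromosomes 1 to 22 and X, an unlocalised contig of chromosome 17 had 3 merged peaks with OTS186935 against 1 with DMSO, and the mitochondrial genome had 3 against 1. An unlocalised contig of chromosome 22 had 5 with doxorubicin against 1 with DMSO, and another contig, of no known chromosome, had 3 with OTS186935 and 3 with doxorubicin against 1.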

How the results depend on the processing

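A common p limit for all lists, matching on local background, 2 ways of counting genes that share a peak once, local shifts and matching on nearest gene length were chosen only after the data had been seen. The order of the libraries, from most peaks and genes with DMSO to fewest with the combination, held as deposited, at −log10 q of 5 and 10, after thinning, with a common p limit and, for genes, with lists of equal length, where 3341 and 2946 genes stood at the ends. Neither keeping all contigs nor a common p limit moved a number of peaks by as much as 1.5 times. Stricter limits and lists of equal length hold fewer peaks by construction, and wider windows more; for the other values below the cause was not tested. In what follows, q 5 and q 10 are the limits on −log10 q, equal the lists of equal length, wide the windows of 2.5 kb, reciprocal the overlap of 50%, joined the peaks within 1 kb joined and thinned the lowest background. The number of peaks, DMSO, was 18655 (q 5) and 1765 (q 10). The number of peaks, OTS186935, was 10592 (q 5) and 724 (q 10). The number of peaks, doxorubicin, was 4762 (q 5) and 232 (q 10). The number of peaks, combination, was 2475 (q 5) and 36 (q 10). The percent of DMSO peaks found in OTS186935 was 26.5 (q 5), 19.7 (q 10), 45.2 (joined), 42.9 (equal), 44.9 (thinned) and 37.6 (reciprocal). The percent of DMSO peaks found in doxorubicin was 14.1 (q 5), 8.27 (q 10), 35.8 (joined), 40.3 (equal), 35.7 (thinned) and 28.3 (reciprocal). The percent of DMSO peaks found in combination was 6.56 (q 5), 1.36 (q 10), 24.2 (joined), 35.8 (equal) and 18.4 (reciprocal). The percent of doxorubicin peaks found in combination was 11.7 (q 5), 6.9 (q 10), 34.6 (equal), 26.4 (thinned) and 21.6 (reciprocal). The percent of OTS186935 peaks found in combination was 8.25 (q 5), 3.04 (q 10), 26.2 (joined), 35.8 (equal), 24.8 (thinned) and 20.2 (reciprocal). The percent of peaks at gene ends, DMSO, was 8.77 (q 5), 8.9 (q 10) and 15.7 (wide), and the percent of peaks in terminal 5 Mb, DMSO, 34.6 (q 10) and 18.1 (equal). The percent of peaks at gene ends, OTS186935, was 9.02 (q 5), 9.53 (q 10), 8.46 (equal) and 14.9 (wide), and the percent of peaks in terminal 5 Mb, OTS186935, 56.6 (q 10) and 18.1 (equal). The percent of peaks at gene ends, doxorubicin, was 8.74 (q 5), 6.03 (q 10), 8.4 (equal) and 14.1 (wide), and the percent of peaks in terminal 5 Mb, doxorubicin, 62.1 (q 10) and 17.5 (equal). The percent of peaks at gene ends, combination, was 7.43 (q 5), 2.78 (q 10) and 15 (wide), and the percent of peaks in terminal 5 Mb, combination, 50 (q 10). In all, genes with a gene-end peak, DMSO, numbered 2091 (q 5), 202 (q 10) and 3341 (equal). In all, genes with a gene-end peak, OTS186935, numbered 1166 (q 5), 86 (q 10), 8794 (wide) and 3043 (equal). In all, genes with a gene-end peak, doxorubicin, numbered 522 (q 5), 19 (q 10) and 6909 (wide). In all, genes with a gene-end peak, combination, numbered 223 (q 5), 2 (q 10) and 4709 (wide). For OTS186935 and DMSO, genes with a gene-end peak in OTS186935 and not in DMSO numbered 540 (q 5), and genes with a gene-end peak in DMSO and not in OTS186935 1465 (q 5) and 1647 (equal). For doxorubicin and DMSO, genes with a gene-end peak in doxorubicin and not in DMSO numbered 208 (q 5), and genes with a gene-end peak in DMSO and not in doxorubicin 1777 (q 5) and 1742 (equal). For combination and DMSO, genes with a gene-end peak in combination and not in DMSO numbered 97 (q 5) and 1433 (equal), and genes with a gene-end peak in DMSO and not in combination 1965 (q 5) and 1828 (equal). For combination and doxorubicin, genes with a gene-end peak in combination and not in doxorubicin numbered 165 (q 5), and genes with a gene-end peak in doxorubicin and not in combination 464 (q 5) and 1493 (equal). For combination and OTS186935, genes with a gene-end peak in combination and not in OTS186935 numbered 119 (q 5) and 1452 (equal), and genes with a gene-end peak in OTS186935 and not in combination 1062 (q 5) and 1549 (equal). Shares kept outside the central 95% of random lists numbered 5 of 51 as planned: immediate early, zinc finger and ribosomal protein genes in doxorubicin, histones in OTS186935 and interferon response genes in the combination. The shares of the histones and the interferon response genes equalled the lower edge of that range. Windows of 2.5 kb left 5 below and 1 above: immediate early and ribosomal protein genes in doxorubicin (3.44) were no longer outside, while ribosomal protein genes in OTS186935 (1.97) and, in the combination, leiomyosarcoma-altered genes (2.08) and histones (98.4) were. Thinning gave 6, adding immediate early genes in the combination (1.36). A common p limit gave 4, without histones. Matching on local background gave 4, without zinc finger and ribosomal protein genes and with immediate early genes in OTS186935 (2.02). List genes that share a peak counted once, by their mean, gave 6, without histones (10.5) and with H3K9 genes in OTS186935 (2.48) and ribosomal protein genes in the combination (2.3), which share none and moved with the random lists. Another count took a peak as kept if any gene at it, in the list or not, had a peak in both, and so changed what kept means even for lists without shared peaks. It gave 3, without histones (9.65) and ribosomal protein genes (2.69). At −log10 q of 5 lists had few genes left and only 3 of 45 shares could have lain below 2.5, so that 0 did so says little; as planned 45 of 51 could. Of 141 genes named or shown as list examples, 46 had a gene-end peak in as many libraries at −log10 q of 5, 120 with windows of 2.5 kb and 135 after thinning. Local shifts in place of random placement raised all 12 shares expected at random, 1.58 to 4.84% against 0.956 to 2.85%. Transcript start sites as an alternative to gene ends were not run, since the gene table lists no transcripts. With summits of few fragments, a missing peak means that none was detectable at this depth.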

Other observations

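Gene-end peaks were not confined to lists for the cell type of the line. Epithelial genes had 10, 9, 8 and 5 of 15 in DMSO, OTS186935, doxorubicin and the combination, with CDH1, the E-cadherin gene (6.29-fold), and EPCAM (6.02-fold) among them in DMSO. They lay at percentiles 98.1, 99.4, 99.6 and 96.5 of random lists of all genes. Neuronal genes had 7, 6, 7 and 7 of 12, at percentiles 90.8, 93.6, 99.6 and 99.97. Immune genes had 6, 5, 6 and 3 of 15, and endothelial genes 5, 6, 4 and 3 of 12. Olfactory receptor genes, mostly silent outside sensory tissue, had 28, 24, 21 and 12 of 390, below every random list in each library.

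Of the 100 peaks of highest fold in each library, 52 lay in the terminal 5 Mb of chromosomes in DMSO, 61 with OTS186935, 37 with doxorubicin and 16 with the combination. The order was another at a limit on −log10 q, which also takes other numbers of peaks (1765, 724, 232 and 36): at −log10 q of 10 or more, the percent of peaks in terminal 5 Mb, DMSO, was 34.6, the percent of peaks in terminal 5 Mb, OTS186935, 56.6, the percent of peaks in terminal 5 Mb, doxorubicin, 62.1 and the percent of peaks in terminal 5 Mb, combination, 50. On chromosome X and chromosome 4, DMSO peaks were kept more often than matched peaks in each treated library, with ratios of 1.15, 1.19 and 1.24 for X, and on 17 and 22 less often, with 0.93, 0.86 and 0.83 for 17. These comparisons share the DMSO library, so part of their likeness can come from it.

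A hypothesis set after the counts had been seen was that the ends of highly expressed genes kept fewer peaks. Ribosomal protein genes lay at percentiles 3.45 with OTS186935, 1.58 with doxorubicin and 3.0 with the combination, the highest being 3.45. They were below 2.5 in doxorubicin only, and matching on local background as well put them at 8.21, 2.79 and 7.85, which left no library below 2.5. With genes that share a peak counted once, which changes only the random lists here since no ribosomal protein genes share a DMSO peak, they lay at 3.02, 1.21 and 2.3. Windows of 2.5 kb put them at 1.97, 3.44 and 30.8, below 2.5 in OTS186935 only. The values thus gave no clear support to the hypothesis and did not exclude it, and no expression data were used here.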
